A study of Mus musculus with 15 samples.

How the data were processed

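RNA was measured in livers of 15 male C57BL/6J mice that carried floxed alleles of Gata4, a zinc finger transcription factor. Per the labels, mice of 8 weeks of age received an adeno-associated virus of serotype 8 (AAV8). It either carried Cre under the Tbg promoter, which is active in hepatocytes (Gata4LKO, called knockout here), or was empty (control). Livers were taken 7 days later, after a fast of 12 h or after a fast of 12 h and refeeding for 12 h with a diet of 69% sucrose and 10% fat. The labels gave 4 fasted control, 4 fasted knockout, 4 refed control and 3 refed knockout samples. Each sample has its own title, and the titles of a group share a number whose meaning is not stated. Any effect of a shared cage, litter, day or hour of collection would therefore coincide with the group. The deposited p-values of single genes measure the spread between these samples.

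Per the labels' protocols, total RNA was extracted with TRIzol and RNeasy columns and libraries were made with a stranded KAPA kit. Per the submitters' processing notes, the authors used FastQC, STAR 2.6.0c, the mm10 genome and DESeq2. The read counter, its strand setting and the gene annotation are not given in the sources used here. The values analysed were a table of results that the authors deposited, named for genotype, with 24965 genes and no values per sample. Per the file headers, its mean is an averaged expression signal, namely counts divided by size factors and averaged over libraries by the authors. Per the file headers, the authors' effect is a log2 fold change with its standard error on the log2 scale. The deposited Wald score equals the log2 fold change divided by its standard error to 6 decimals. Deposited p-values are of that Wald test by the authors with DESeq2, and the deposited adjusted p equals a Benjamini-Hochberg adjustment over the 13335 genes that have one. A further 11605 genes had a p and no adjusted p, 5 had an estimate and no p, and 20 had a mean of 0. The lowest mean among genes with an adjusted p was 8.20 normalized counts. Missing values stayed missing, and the table was not refitted.

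The header does not state which groups were compared, so this was worked out from genes with a single read. The 15 smallest nonzero means repeat over genes, as 1 read in 1 of 15 libraries would give, and their inverses gave relative size factors between 0.912 and 1.11. The log2 fold changes of these genes fell into 4 sets, of 4, 4, 4 and 3 libraries, as the groups do. A negative binomial model with a weak ridge penalty was fitted to such single reads under 32 readings of the table (main effects or interaction models, each reference group and each contrast). Of these, 2 gave the deposited estimates and standard errors within 1e-06, and the closest of the others differed by 2.79e-05. Both take all 15 libraries in an interaction model with fasted control livers as the reference: knockout minus control in fasted livers, or refed minus fasted in control livers. The single reads cannot separate these 2 readings, because the groups they concern have equal sizes. The first was taken because the deposited result is named for genotype. It was also taken because 0 genes were called in the lists of fatty acid oxidation and of the fasting response, as given in the report. This does not hold for every gene that feeding controls, since 4 genes of fatty acid synthesis were called, all lower. The direction in every statement below rests on this choice of reading.

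A gene was called with a deposited adjusted p under 0.05, in either direction. Before the data were examined, 32 gene lists were fixed (23 of pathways and 9 of cell types), together with the tests, the alternatives and the rule for named genes. The planned tests of values per sample could not be run on this table, so the planned reading of a deposited comparison was used. For each list, members called in each direction were counted over all genes tested and again adjusted over the list alone. Lists with at least 5 tested members, 30 in all, were tested with cameraPR (limma 3.58.1 in R 4.3.3) on the Wald statistic against all other tested genes. It was run with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. An estimated correlation needs values per sample and was not computed. The median of a list was also placed among the medians of 10000 random lists matched on mean in 20 bins. Both the list test and the random lists compare genes with genes, with the correlation between genes preset or ignored. Their results therefore do not measure the spread between livers. Where a symbol stood on more than 1 row, the most abundant row was used. The rule named Gata4, Gata6, Abca1, Abcg5, Abcg8, Srebf1, Cd36, Fasn, Cyp7a1, Hamp and Hnf4a. It also named the 8 largest rises and 8 largest falls among called genes with a given name and a mean of at least 100, and up to 4 members with the smallest p of each list with a called member. This gave 79 genes, of which the text describes a part, and some are not reported here. Other genes named were chosen after their values were seen.

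A further 6 lists were written after values had been seen, and were tested apart: carboxylesterases, antioxidant and conjugation enzymes linked to the transcription factor NRF2, a subset of that list, the urea and methionine cycles, complement, and acyl-CoA synthetases and acyltransferases. Gene positions were taken from GENCODE for mm10, to which 24944 of the 24965 genes matched by identifier. GC content and length of the longest transcript came from the same release, which may differ from the annotation the authors used. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

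The tests were tested on simulated data with the standard errors of the 13335 tested genes. With 200 genes changed by 1 on the log2 scale, 80.2% were recovered and 5.14% of calls were false, over 20 simulations. In 100 simulations with the Wald statistics of 5 lists shifted by 1, 94.4% of shifted lists and 0.44% of unshifted lists were called. The simulated errors were independent between genes, which real errors are not. Total counts per sample were not used here. Precision is set by the deposited standard errors, whose median was 0.11 for the 8875 tested genes with a mean of at least 100 and 0.32 for the 4460 below it. Alternatives were other sets of genes for the adjustment, other thresholds, a minimum effect, named genes alone, and other settings of the list test. A correction for GC content and length was added after seeing the data.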

Results

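The deposited comparison covered liver RNA of fasted mice, with 4 livers labelled knockout (Gata4LKO) and 4 labelled control. The model behind it also took in 7 refed livers. It addresses what changed in the liver of fasted mice 7 days after a hepatocyte-directed Cre virus was given to remove Gata4. Refed livers, the response to feeding and its dependence on genotype were not analysed here, since the table holds no values per sample. Relative size factors of the 15 libraries lay between 0.912 and 1.11, and the mean normalized counts of all genes summed to 1.80e+07. Log2 fold changes are knockout minus control, each with the standard error of the authors' model.

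Gata4 itself was not lower in livers labelled knockout. In the authors' deposited table, Gata4 (ENSMUSG00000021944, chromosome 14, 63198922 to 63271692, mm10) had a mean of 326.9 normalized counts and a log2 fold change of 0.31 ± 0.15 (SE), with an adjusted p of 0.361 by the authors' DESeq2 Wald test with Benjamini-Hochberg adjustment. The 95% interval of that change ran from 0.03 to 0.60 in the authors' deposited table. The labels do not say which exons are floxed, and a count over the whole gene does not test a deletion of part of it. The Cre virus was directed at hepatocytes, while liver RNA also holds transcripts of other cells. How much of the Gata4 count came from such cells was not measured. The related factor Gata6 had a log2 fold change of 0.18 ± 0.13 (SE) in the authors' deposited table and was not called. Directions below therefore refer to livers by their labels, and to the reading of the table given with its processing.

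By the set tests given with each list, the cholesterol synthesis, fatty acid synthesis, interferon-response and clock lists lay lower than other genes in livers labelled knockout. The p53 and xenobiotic metabolism lists lay higher. These tests compare genes with genes and do not measure the spread between livers. By the deposited test of single genes, 15 of 25, 4 of 20, 6 of 29 and 3 of 20 members of the first 4 lists were called lower. In the p53 and xenobiotic metabolism lists, 6 of 19 and 2 of 24 were called higher. In all, 292 of 13335 tested genes were called (2.19%), 78 higher and 214 lower, so that 73.3% of calls were lower. Changes of at least 1 on the log2 scale were seen in 15 of the higher and 59 of the lower genes. Among all tested genes the median log2 fold change was 0.01. Of the called genes, 267 were protein coding, 16 were long noncoding RNAs and 8 were pseudogenes. By the authors' DESeq2 Wald test, 1518 tested genes had an unadjusted p under 0.05.

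**Figure D1:**
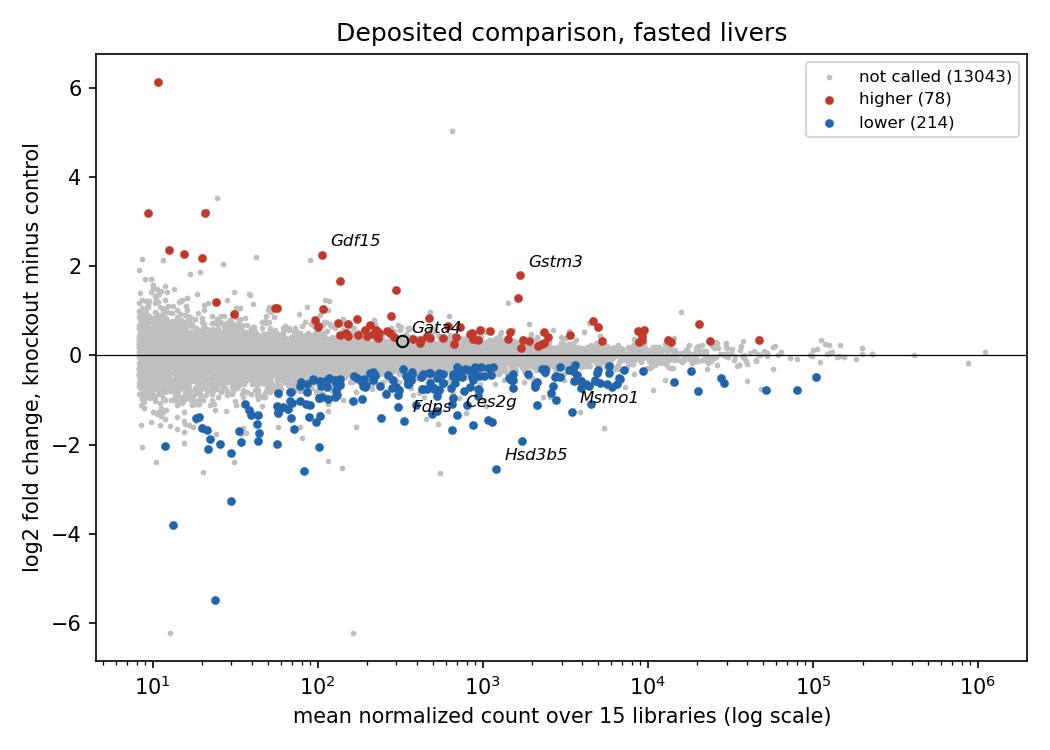
Each point is a tested gene, with its mean normalized count over 15 libraries (horizontal, log scale) against its deposited log2 fold change, knockout minus control in fasted livers (vertical). Red points are the 78 genes called higher, blue points the 214 called lower and grey points the genes not called; the open circle marks Gata4, which lies above 0.

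The largest rises under the naming rule included Gdf15, a stress-induced hormone, and Gstm3, a glutathione transferase. In the authors' deposited table their log2 fold changes were 2.26 ± 0.39 (SE) for Gdf15 (ENSMUSG00000038508, chromosome 8, 70629393 to 70632456) and 1.79 ± 0.20 (SE) for Gstm3 (ENSMUSG00000004038, chromosome 3, 107963696 to 107969283). Next in the authors' deposited table stood Abcc4, an export pump of conjugated compounds, at 1.67 ± 0.24 (SE), Serpina7, which encodes thyroxine-binding globulin, at 1.46 ± 0.27 (SE), and Acnat2 at 1.29 ± 0.20 (SE). The largest falls were of Hsd3b5, a male-biased steroid dehydrogenase, the desmoglein gene Dsg1c, and Rgs16, a regulator of G protein signalling. Their log2 fold changes in the authors' deposited table were -2.54 ± 0.35, -2.04 ± 0.21 and -1.92 ± 0.52 (SE). The carboxylesterase Ces1g, at -1.55 ± 0.35 (SE) in the authors' deposited table, belongs to a family of similar genes that can share reads, as do Hsd3b5, Selenbp2, Cyp4a12b and the Gstm genes, and the values of such genes are uncertain to that extent.

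Genes of cholesterol synthesis and uptake fell together. Of 25 tested members, 15 fell, 0 rose and 10 did not pass the test; adjusted over the list alone, 19 fell. The median log2 fold change was -0.60, below all 10000 matched random lists, and the set test gave an adjusted p of 5.06e-31 (cameraPR). In the authors' deposited table Fdps, the farnesyl diphosphate synthase gene (ENSMUSG00000059743, chromosome 3, 89093588 to 89101959), changed by -1.46 ± 0.24 (SE), and Msmo1 and Sqle, of the later sterol pathway, by -1.26 ± 0.20 and -1.11 ± 0.19 (SE). The sterol carrier Stard4 was at -0.71 ± 0.12 (SE) in the authors' deposited table.

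LXR targets, genes controlled by the oxysterol receptor, included 4 that fell, 0 that rose and 11 that did not pass among 15 tested. Adjusted over the list alone, 4 fell, and the set test gave an adjusted p of 0.00205 (cameraPR). The log2 fold changes in the authors' deposited table were -0.96 ± 0.15 for Abcg5 and -0.77 ± 0.18 (SE) for Abcg8, the paired exporters of sterols into bile. They were -0.33 ± 0.07 for Abca1, which loads cholesterol onto apolipoprotein A-I, and -0.72 ± 0.21 (SE) for the lipogenic regulator Srebf1 in the authors' deposited table. Srebf1 was not past the threshold with the adjustment over every gene with a p. The list's median was 0.00 (38.04th percentile of random lists), so the list moved through these members, and the rank-based test gave an adjusted p of 0.181 (cameraPR). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 fold change of 0.03 ± 0.39 (SE) in the authors' deposited table and was not called.

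Fatty acid synthesis genes fell in 4 cases, rose in 0 and did not pass in 16 of 20 tested; adjusted over the list alone, 6 fell. The median log2 fold change was -0.17, and the set test gave an adjusted p of 6.95e-05 (cameraPR). Examples in the authors' deposited table were Thrsp at -0.80 ± 0.17, Fasn, the fatty acid synthase gene, at -0.77 ± 0.18, and Acss2 at -0.52 ± 0.15 (SE). Of 25 tested lipoprotein genes 4 fell and 0 rose, also 4 adjusted over the list alone, and these included Apoa1, the main apolipoprotein of high-density lipoprotein, at -0.48 ± 0.11 (SE) in the authors' deposited table. That set test gave an adjusted p of 0.010, against 0.0729 with a preset correlation of 0.05 and 0.240 with ranks (cameraPR). Among 28 tested genes of lipid droplets and fatty acid uptake, 1 rose and 2 fell (2 and 2 adjusted over the list alone), with an adjusted p of 0.974 for the set (cameraPR). The fatty acid binding genes Fabp2 and Fabp1 fell by 1.25 ± 0.18 and 0.50 ± 0.14 (SE) on the log2 scale, and the lipoprotein receptor Vldlr rose at 0.58 ± 0.16 (SE), in the authors' deposited table. Cd36, a fatty acid transporter, had a log2 fold change of 0.04 ± 0.34 (SE) in the authors' deposited table and was not called.

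Genes of fasting metabolism were not called, a fact that was itself used to choose between the 2 readings of the table and is therefore no independent result of the comparison. By the authors' DESeq2 Wald test, 0 of 24 tested genes of fatty acid oxidation and ketogenesis and 0 of 15 of gluconeogenesis and the fasting response passed. At an unadjusted p under 0.05 the numbers were 4 and 0, and adjusted over the list alone 1 and 0. Their medians were 0.01 for both, and the set tests gave adjusted p of 0.761 for both (cameraPR). Pck1, a gluconeogenic enzyme that fasting induces, had a log2 fold change of 0.01 ± 0.82 (SE) in the authors' deposited table, so that its interval, from -1.59 to 1.61, leaves room for large changes. Igfbp1, which fasting induces, had a log2 fold change of 0.27 ± 0.59 (SE) in the authors' deposited table; both genes were named after their values were seen.

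The p53 and DNA damage response list rose. Of 19 tested members 6 rose, 0 fell and 13 did not pass; adjusted over the list alone, 8 rose. The median log2 fold change was 0.39, above all 10000 matched random lists, with an adjusted p of 1.24e-08 (cameraPR). Besides Gdf15, the receptor gene Eda2r stood at 2.17 ± 0.47, the nuclease gene Aen at 0.88 ± 0.17 and Ccng1 (cyclin G1) at 0.57 ± 0.15 (SE) in the authors' deposited table. Cdkn1a, which encodes the cell cycle inhibitor p21, had a log2 fold change of 0.97 ± 0.54 (SE) in the authors' deposited table and did not pass, a gene named after its value was seen. Of 17 tested cell cycle genes, 0 were called by the authors' DESeq2 Wald test, 3 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone (adjusted p 0.472, cameraPR). Of 20 genes of the unfolded protein and integrated stress response, 0 were called by that test, 3 had an unadjusted p under 0.05 and 1 passed adjusted over the list alone (adjusted p 0.698, cameraPR).

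Interferon-response genes fell. Among 29 tested members 6 fell, 0 rose and 23 did not pass; adjusted over the list alone, 11 fell, and 28 of 29 estimates were negative. The median log2 fold change was -0.41, with an adjusted p of 5.30e-12 (cameraPR). The nucleic acid sensor Zbp1 changed by -1.34 ± 0.32, Ifit1, which binds viral RNA, by -1.11 ± 0.27, Irf7 by -0.69 ± 0.18 and the immunoproteasome subunit Psmb8 by -0.69 ± 0.17 (SE) in the authors' deposited table. Kupffer cell and macrophage markers moved the same way, with a median of -0.25 and 14 of 16 estimates negative (adjusted p 0.00782, against 0.0506 for the 10 members with a mean of at least 100, cameraPR). Of these markers 0 were called by the authors' DESeq2 Wald test, 2 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone.

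**Figure D2:**
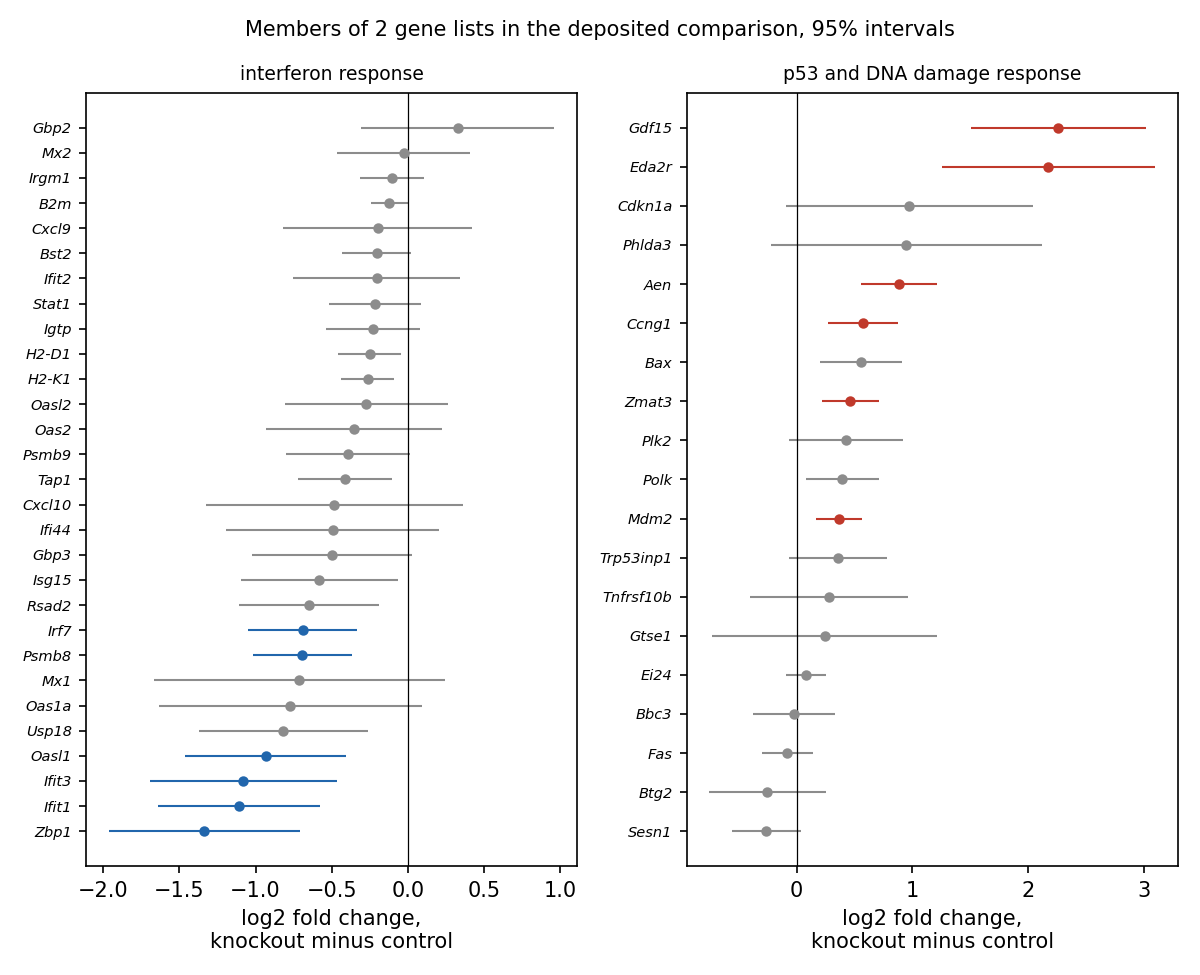
Points are deposited log2 fold changes (knockout minus control, fasted livers) of the tested members of the interferon list (left) and the p53 list (right), with bars for 95% intervals from the deposited standard errors. Red marks genes called higher, blue genes called lower and grey genes not called; 6 of 29 members were called lower and 6 of 19 higher.

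Xenobiotic metabolism genes rose in 2 cases and fell in 0 of 24 tested, both of the Gstm family, and 22 of 24 estimates were positive. Adjusted over the list alone, 6 rose and 1 fell, and the set test gave an adjusted p of 3.69e-07 with a median of 0.25 (cameraPR). Gstm1 stood at 0.70 ± 0.12 (SE) in the authors' deposited table, while the quinone reductase Nqo1, at 0.67 ± 0.21, and Cyp2a5, at 0.97 ± 0.34 (SE), did not pass. Of 25 tested bile acid genes 1 rose, Abcc4, and 2 fell (1 and 3 adjusted over the list alone), with an adjusted p of 0.895 for the set (cameraPR). The fallen genes were Cyp2c70 and Baat, of bile acid hydroxylation and conjugation, at -0.65 ± 0.17 and -0.55 ± 0.10 (SE) in the authors' deposited table.

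Clock genes fell in 3 cases and rose in 0 of 20 tested, with 5 lower and 1 higher adjusted over the list alone, a median of -0.32 and an adjusted p of 0.00116 (cameraPR). These were Bhlhe40, Per3 and Per2, at -0.99 ± 0.15, -0.89 ± 0.24 and -0.75 ± 0.17 (SE) in the authors' deposited table. A difference in the hour of collection between the groups was not tested and could not be told apart from the genotype label. Of 17 male-biased genes 4 fell and 0 rose (7 and 1 adjusted over the list alone), among them Hsd3b5, Selenbp2 and Cyp4a12b. The test called that list lower (adjusted p 0.00391, cameraPR) and its mean was -0.45, but its median was 0.10, and the adjusted p was 0.533 with ranks and 0.0762 without its member of smallest p. Of 8 female-biased genes 0 were called by the authors' DESeq2 Wald test, 1 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone (adjusted p 0.396, cameraPR).

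Among 24 tested liver transcription factor genes, 1 fell, which was also the count adjusted over the list alone (adjusted p 0.761, cameraPR). It was Zfpm1, which encodes the GATA cofactor FOG1, at -0.72 ± 0.16 (SE) in the authors' deposited table. Hnf4a was not called, at 0.10 ± 0.07 (SE) in the authors' deposited table. Of 20 tested genes of iron handling and BMP response 0 were called by the authors' DESeq2 Wald test, 5 had an unadjusted p under 0.05 and 2 rose adjusted over the list alone. That list had a median of 0.18 and an adjusted p of 0.00869, against 0.0598 with a preset correlation of 0.05 (cameraPR). Hamp, the gene of the iron hormone hepcidin, had a log2 fold change of 0.35 ± 0.40 (SE) in the authors' deposited table and was not called. Sinusoidal endothelial markers, of cells that supply BMP ligands, had a median of 0.21 and an adjusted p of 0.0112, against 0.0720 with a preset correlation of 0.05 (cameraPR). Of those 20 markers 0 were called by the authors' DESeq2 Wald test, 6 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone.

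Other lists were not called as sets. Pericentral hepatocyte genes had 1 fall among 16 (2 higher and 4 lower adjusted over the list alone; adjusted p 0.334), the vitamin C pathway gene Gulo at -0.50 ± 0.10 (SE) in the authors' deposited table. Periportal genes had 1 rise among 15, also adjusted over the list alone (adjusted p 0.397), of Etnppl at 0.78 ± 0.19 (SE) in the authors' deposited table. Acute phase genes had 1 rise among 24, also adjusted over the list alone, of haptoglobin (Hp) at 0.35 ± 0.10 (SE) in the authors' deposited table, while the list's median was -0.16 (adjusted p 0.182, against 0.0473 with ranks and 0.0495 without the member of smallest p, cameraPR). The red blood cell list had 1 fall among 6, also adjusted over the list alone, of Alas2 at -0.41 ± 0.12 (SE) in the authors' deposited table (adjusted p 0.438, cameraPR). The adipose list had 1 rise among 6, of Cfd at 3.20 ± 0.96 (SE) with a mean of only 9.36 normalized counts in the authors' deposited table (2 higher and 1 lower adjusted over the list alone; adjusted p 0.396, cameraPR). By the authors' DESeq2 Wald test 0 members were called of extracellular matrix (21 tested), stellate cell (16), cholangiocyte (7), fetal liver (5) and lymphocyte (5) genes, with 2, 0, 0, 1 and 2 at an unadjusted p under 0.05. Adjusted over the list alone, 1 fetal liver gene passed and 0 of the other lists just named, and the adjusted p of these 5 lists were 0.334, 0.196, 0.576, 0.396 and 0.761 (cameraPR). The median, mean and test differed in sign for the uncalled lists of cell cycle, lymphocyte, fatty acid oxidation, lipid droplet and stress response genes. Neutrophil and pancreas genes had 2 and 1 tested members, too few for a set test, and 0 were called or had an unadjusted p under 0.05 by the authors' DESeq2 Wald test.

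Control animals received an empty virus, so that the presence of Cre coincides with the genotype label. With the adjustment taken over every gene with a p, Acss2, Fabp1, Alas2 and Cfd also no longer passed. Any cage, litter, day or hour of collection shared by the animals of a group coincides with it in the same way.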

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

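The correction for GC content and length was chosen after seeing the data; all other settings were planned. No paired analysis was possible because the deposited table holds no values per sample. For the same reason leaving out single livers, other splits of the samples, other normalizations and filters, a pseudocount and fits of the compared groups alone were not run. Of the 292 calls, 223 remained with the adjustment over every gene with a p, 291 over genes with a mean of at least 10, 233 over genes with a mean of at least 100, 269 among named genes and 276 after the GC and length correction. Of 79 genes named by the rule, 7 lost their call with the adjustment over every gene with a p (Srebf1, Acss2, Fabp1, Alas2, Cfd, Nudt7 and Treh), and 14 at 0.01; Nqo1 and Nfil3 passed with the adjustment over genes with a mean of at least 10 or 100. Stricter or looser thresholds moved counts by construction: 167 genes (38 higher, 129 lower) at 0.01, 132 higher at 0.1, 191 (41 higher) with a log2 change of at least 0.5, and 74 (15 higher, 59 lower) with at least 1. Of 12 lists past the threshold, 6 kept their side and direction under all 5 alternatives. These were the cholesterol synthesis, fatty acid synthesis, interferon-response, clock, p53 and xenobiotic metabolism lists. With a preset correlation of 0.05, adjusted p rose to 0.0729 for lipoproteins, 0.0598 for iron handling and 0.0720 for sinusoidal endothelial markers, and ranks gave 0.181 for LXR targets, 0.240 for lipoproteins, 0.533 for male-biased genes and 0.0473 for acute phase genes, now past it. Members with a mean of at least 100 gave 0.0506 for macrophages. Without the member of smallest p, male-biased genes had 0.0762 and acute phase genes 0.0495. Directions turned only in lists not called: lipid droplets (0.795 with ranks, 0.615 without that member, 0.956 after correction), fatty acid oxidation (0.958 at a mean of at least 100, 0.977 without that member), and at a mean of at least 100 transcription factors (0.963), stress response (0.960) and cell cycle (0.276). Among lists added after seeing the data, urea cycle (0.796) and acyl-CoA genes (0.918) turned with ranks. Bile acid genes (0.637) and red blood cell genes (0.977) turned without that member. The cause of the other changes was not tested. Under a mean of 100 the median standard error was 0.32, which limits what low genes can show.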

Other observations

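The 6 gene lists described first and all tests of explanations were chosen after results were seen. Enzymes of the antioxidant and conjugation response linked to the transcription factor NRF2 were higher: 7 of 19 tested members rose, 0 fell, and all 19 estimates were positive, with a median of 0.55 (adjusted p 1.89e-23, cameraPR over the 6 lists). Some members had been seen as called before that list was written, so it is not independent evidence. The 9 tested members whose values had not been displayed by then, set apart after the sum of the list was known, had a median of 0.20, with 1 called and 9 of 9 positive (adjusted p 6.53e-05, cameraPR). Since all 19 estimates were positive, any subset would be too, so these 9 are not independent evidence either. Members of the full list outside these 9 included Gsta4 at 0.66 ± 0.12, Ephx1 at 0.57 ± 0.13 and Srxn1 at 0.55 ± 0.14 (SE) in the authors' deposited table.

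Carboxylesterase genes went both ways, with 2 higher and 3 lower of 13 tested (adjusted p 0.00983, against 0.643 with ranks and 0.487 without the member of smallest p, cameraPR). The gene with the smallest p of the table was Ces2g, at -1.34 ± 0.14 (SE) in the authors' deposited table. Complement genes had 1 higher and 4 lower of 21 (adjusted p 1.68e-05, cameraPR), urea and methionine cycle genes 0 higher and 3 lower of 15 (adjusted p 0.0790), and acyl-CoA synthetases and acyltransferases 1 higher and 4 lower of 16 (adjusted p 0.118, against 0.00730 without the member of smallest p, Acnat2, which rose, and 0.918 with ranks). The last 2 lists had medians above 0 and means below it. Otc, of the urea cycle, stood at -0.70 ± 0.08 and Hsd11b1, which activates glucocorticoids, at 0.54 ± 0.06 (SE) in the authors' deposited table. On chromosome 8, 31 of 737 tested genes were called against 16.1 from the share over all chromosomes (Fisher's exact test, two-sided, adjusted p 0.0124 over chromosomes), and 5 of them were carboxylesterases. Chromosome 14, which carries Gata4, had 12 called genes against 9.68 (adjusted p 0.790).

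As a list, p53 response genes had higher estimates in livers labelled knockout, by a test that does not measure the spread between livers. After the median change of genes of like GC content and length was taken off, the adjusted p of the list was 8.20e-09 (cameraPR). The medians taken off lay between -0.068 and 0.060, against a list median of 0.39, so that test could change little. The small medians argue against a GC content or length bias as large as the list's change. A response to Cre or its vector, and not to loss of Gata4, may also raise these genes; it cannot be told apart from the genotype, because 0 groups received Cre with Gata4 intact. An effect of Gata4 loss itself stays open and untested, as does any effect shared by the animals of a group.

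As a list, cholesterol synthesis genes had lower estimates in livers labelled knockout, with the same limit of the set test. After the same correction the adjusted p was 3.91e-31 (cameraPR). The medians taken off lay between -0.068 and 0.060, against a list median of -0.60, so that test could change little. The small medians argue against a GC content or length bias as large as the list's change. A deeper fast in these animals could lower sterol synthesis. The mean log2 change of the fasting response list was 0.046, with a 95% interval from -0.60 to 0.69 if errors are shared within the list, which is too wide to decide, and genes of this list had also been used to choose the reading of the table. Fatty acid synthesis genes, which feeding also controls, were lower as a list (median -0.17, adjusted p 6.95e-05, cameraPR), which goes with a deeper fast. Genes of fatty acid oxidation and ketogenesis, also used to choose the reading, had a median of 0.01 (adjusted p 0.761, cameraPR). These lists do not decide the question, and the genotype stays among the open explanations.

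As a list, interferon-response genes had lower estimates in livers labelled knockout, with the same limit of the set test. After the correction the adjusted p was 8.07e-12 (cameraPR). The medians taken off lay between -0.068 and 0.060, against a list median of -0.41, so that test could change little. The small medians argue against a GC content or length bias as large as the list's change. Fewer macrophages may lower such transcripts, since macrophage markers were lower as a list. That list was not past the threshold among members with a mean of at least 100 (adjusted p 0.0506, cameraPR). Among such members the medians were -0.26 for 14 interferon genes and -0.17 for 10 macrophage markers. Over all tested members, the mean change of the interferon list lay below that of the macrophage list (difference -0.27). Loss of transcripts made in macrophages would not alone give such a difference, but interferon-response transcripts of other cells are not covered by that argument. The 95% interval of the difference, from -0.90 to 0.36 with errors shared within each list, also leaves the question open. An interval across genes, computed first, ran from -0.44 to -0.10, but it treats co-regulated genes as independent. A difference between the empty and the Cre virus coincides with the genotype and was not tested.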
